A study of Mus musculus with 4 samples.

How the data were processed

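Single-cell suspensions of 4 mouse placentas at E13.5 were profiled on the 10x Genomics Chromium, a droplet system in which each captured RNA molecule carries a cell barcode and a unique molecular identifier (UMI) and is read near the 3-prime end of its transcript. Each sample was 1 placenta, so the placenta was the replicate: 2 control placentas and 2 placentas labelled as Pl1-Cre knockouts of Gata2 and Gata3. Per the labels' protocols, the tissue was digested with enzymes and red cells were depleted with an antibody against Ter-119. That depletion limits what can be said of the erythroid share. Per the submitters' processing notes, reads were aligned and counted with Cell Ranger 3.0.2 on GRCm38. The deposited values are UMI counts per gene and barcode, and the authors' tables hold all 6794880 barcodes and 31053 genes, before any selection of cells. A cell annotation by the authors was not used here. The choice of barcodes, the clusters and the class names were therefore rebuilt here, and shares of cells depend on that rebuilding.

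Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. Of 6425, 6608, 8504 and 7695 barcodes with 1000 UMIs in control 1, control 2, KO 1 and KO 2, the gene minimum removed 727, 1098, 1099 and 908. The mitochondrial limit removed a further 141, 54, 471 and 225. Doublets were scored against simulated doublets within each sample, and the highest scores were removed at a rate of 0.8% per 1000 cells, which was 4.44, 4.36, 5.55 and 5.24% of the barcodes. Counts were scaled to 10000 per cell and log-transformed. Then 2000 variable genes, 30 principal components, 20 nearest neighbours and the Leiden method at resolution 1 gave 43 clusters (seed 1). A cluster was named X-like from 22 marker lists when at least 3 markers of that class were among its top 100 genes by fold in CPM (counts scaled to a common library total) and its leading genes did not go against the name. 7 clusters stayed unnamed. Gata2 and Gata3 served as no marker. The RNA of barcodes with under 100 UMIs was used as the profile of free RNA, which floats in every droplet and adds UMIs to cells that do not express a gene. Where free RNA was subtracted, the globin UMIs of a class set the amount, so globin made by the class itself inflates it.

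Raw UMI counts were summed per placenta and class where each placenta had at least 20 cells, except for B-like cells, which were not fitted. The sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05, R 4.3.3). All log2 folds are KO-labelled minus control, with their standard error (SE), and CPM values are TMM-scaled. Class shares were tested with the same quasi-likelihood test on numbers of cells, with the total of kept barcodes as library size. The difference of the group effect between trophoblast-like and endothelial-like cells was an edgeR interaction term with the placenta as block. 26 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01. The same test with an estimated correlation and fry stood beside it, and no camera call in trophoblast-like, giant cell-like or endothelial-like cells held with an estimated correlation. An exact permutation of 2 against 2 placentas cannot give a p under 0.333, so every p comes from models that share the spread across genes or classes.

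In each class the text names Gata2, Gata3 and Prl3d1, and the 10 genes with the largest log2 fold in each direction. Those had to pass the threshold, hold both KO-labelled placentas outside the range of both controls and average at least 20 CPM. Mitochondrial, ribosomal protein, globin and sex-linked genes were left out of that rule. From each called list up to 4 members with the smallest p are named. The groups, tests, marker lists, gene lists, this rule and the other settings to be tried were fixed before the data were examined. A group with a count of 0 is given a bound from a floor of 3 counts over the group. A group with 1 to 3 counts is given a ratio with a 95% interval that covers counting error only. Gene positions came from GENCODE M21 on GRCm38, in which 30934 of the 31053 gene identifiers were found.

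The tests were checked on simulated counts with 200 changed genes drawn from the real means and library sizes. As many genes were raised as lowered, and no trend with transcript length was simulated. The rates below therefore do not give the error of fits such as the trophoblast-like one, with 3402 genes called higher and 3273 lower. In the trophoblast-like fit (13276 genes) 99% of 2-fold and 100% of 4-fold changes were recovered, and 9.95% of the calls were false. In the giant cell-like fit (9497 genes) 94% and 99% were recovered, with 8.10% of the calls false. In the endothelial-like fit (11689 genes) 37% and 78% were recovered, with 10.9% of the calls false. In the progenitor-like fit (9759 genes) 72% and 100% were recovered, with 8.02% of the calls false. In the macrophage-like fit (5211 genes) 20% and 79% were recovered, with 9.17% of the calls false. The share test recovered 96% of 4-fold changes in 50 simulations of 15 classes, and called 2.33% of unchanged classes.

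The other settings were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, the replicate number as a block, leaving out each placenta, a stricter cell filter (2000 UMIs and 1000 genes), a mitochondrial limit of 10%, no doublet removal, a Leiden resolution of 0.5 and subtraction of free RNA. Settings added after the data were seen were libraries thinned to equal totals, removal of 6 clusters poor in mitochondrial RNA, endothelial-like clusters with at least 20 cells in each placenta alone, removal of the trend of each library with transcript length (loess, span 0.3), and counting of unnamed clusters 31 and 38 as monocyte-like or dendritic-like. Clusters counted as poor in mitochondrial RNA had a median mitochondrial share under 0.5% and also Malat1 under 1000 CPM. Clusters 17, 27 and 28 had medians of 0.350, 0.174 and 0.387% but more Malat1, and were not removed. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 did the rest. The labels give no sequencing date or batch, and all libraries of a group share 1 genotype label, so a batch that follows the groups cannot be told apart from the genotype.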

Results

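Placental cells from 2 control and 2 KO-labelled mouse embryos at E13.5 were compared. The KO label stands for conditional loss of Gata2 and Gata3, a pair of GATA transcription factors of trophoblast, through a Cre recombinase driven by placental lactogen 1 (gene Prl3d1), a hormone gene of trophoblast giant cells. The series concerns a trophoblast layer set between placental endothelium and blood formation, so the comparison asks how trophoblast, endothelial cells and blood progenitors differ when both factors are targeted in trophoblast. The libraries held 58051230 and 42644693 UMIs in control 1 and control 2, against 151358779 and 110323683 in KO 1 and KO 2. After filtering, 5310 and 5218 barcodes were kept in the controls and 6549 and 6218 in the KO-labelled placentas. Their median depth was 3219.5 and 2403.5 UMIs in the controls and 4683 and 3970.5 in the KO-labelled placentas.

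Measures in free RNA and across cell classes separated the groups. Mitochondrial transcripts made up 4.36 and 3.34% of the free RNA in the controls and 11.0 and 10.7% in the KO-labelled libraries. Within trophoblast, 6 clusters poor in both mitochondrial RNA and Malat1 held 21.5 and 34.8% of all kept barcodes in the controls and 40.6 and 51.2% in the KO-labelled placentas. In control 1, control 2, KO 1 and KO 2 these were 1142, 1815, 2662 and 3186 of 2058, 2550, 3320 and 3605 trophoblast-like cells. Short transcripts were lower in the KO-labelled placentas in each of the 12 classes and subtypes fitted, of which giant cell-like and spongiotrophoblast-like cells are parts of trophoblast. B-like cells (177 and 164 control, 180 and 273 KO-labelled) were not fitted. Among genes whose longest transcript has at most 500 nt, the median log2 fold was -1.42 in trophoblast-like cells (144 genes, 92 lower and 3 higher), -1.12 in sinusoidal giant cell-like cells, -1.32 in endothelial-like cells, -1.80 in progenitor-like cells and -1.48 in neutrophil-like cells. Of 8120 genes tested in at least 6 classes, 70 were lower by at least 1 on the log2 scale in every class in which they were tested. These included Lepr (8 classes), Apoc1 (8 classes), Notch2, AC160336.1 (12 classes each), Rpgrip1 (10 classes), Snhg9 (9 classes), Wfdc17 (11 classes) and Cox7a1 (6 classes). Ppbp, a platelet chemokine tested in 6 classes, was the 1 gene among the 8120 that was higher by at least 1 in every class in which it was tested.

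**Figure D1:**
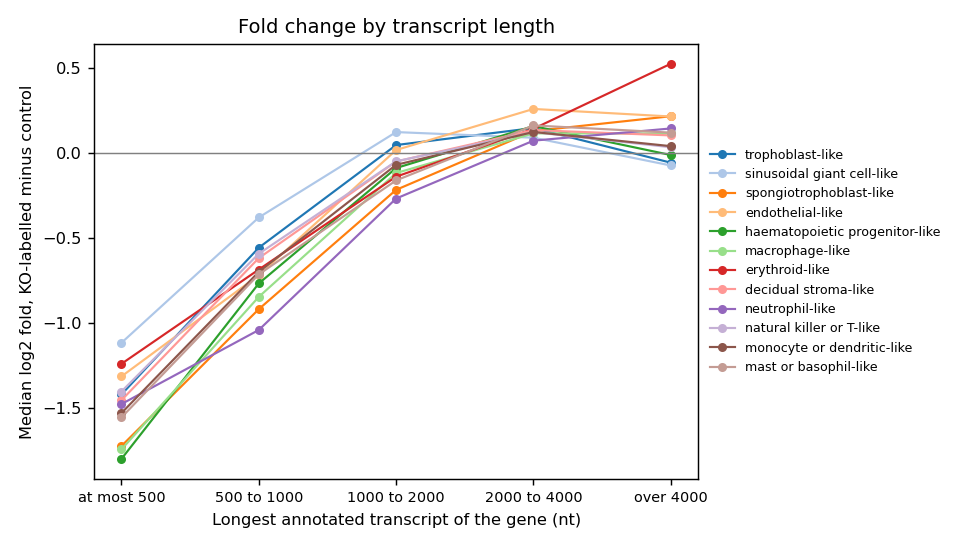
Median log2 fold of gene expression (y axis, KO-labelled minus control, 2 placentas each) by the length of the longest annotated transcript of a gene in nt (x axis), with 1 line per cell class. Genes of at most 500 nt lie below 0 in every class plotted, at -1.42 in trophoblast-like cells.

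Gata2 differed little between the groups in trophoblast-like cells and Gata3 did not pass the test there. Gata2 (ENSMUSG00000015053, chromosome 6, 88193891 to 88207032, plus strand) averaged 143 ± 0.476 CPM (SD, n = 2) in control and 119 ± 0.406 CPM (n = 2) in KO-labelled trophoblast-like cells, a log2 fold of -0.27 (SE 0.096, edgeR adjusted p = 0.0476). Gata3 (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034, minus strand) averaged 58.1 ± 5.14 and 63.1 ± 2.24 CPM (0.12, SE 0.11, adjusted p = 0.383). In sinusoidal giant cell-like cells Gata2 averaged 207 and 169 CPM (-0.29, SE 0.097, adjusted p = 0.0464) and Gata3 93.9 and 89.9 CPM (-0.06, adjusted p = 0.742). Prl3d1 (ENSMUSG00000057170, chromosome 13, 27094190 to 27100258, plus strand) averaged 3.46 and 3.15 CPM in trophoblast-like cells (-0.17, SE 0.37, adjusted p = 0.722). Outside trophoblast, Gata3 fell in progenitor-like cells from 19.2 ± 1.61 to 3.18 ± 1.21 CPM (-2.74, SE 0.38, adjusted p = 0.00108). Gata2 averaged 103 and 102 CPM in those cells (0.03, adjusted p = 0.934), and in endothelial-like cells 75.0 and 46.8 CPM (-0.75, adjusted p = 0.113). The call of Gata2 in trophoblast-like cells ended when any of the 4 placentas was left out (adjusted p between 0.0946 and 0.245), that in giant cell-like cells without control 1, control 2 or KO 2 (0.189, 0.126 and 0.189), and that of Gata3 in progenitor-like cells without doublet removal (-1.20, adjusted p = 0.0995). With free RNA subtracted Gata3 in progenitor-like cells stood at -7.93 (adjusted p = 0.00455), from 34 and 24 counts left in the controls and 0 in both KO-labelled placentas, so that size is not a measured one. The place of the deleted part relative to these 3-prime reads is not given in the sources used, and Gata3 overlaps 9230102O04Rik on the same strand, so these values neither show nor exclude the deletion.

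**Figure D2:**
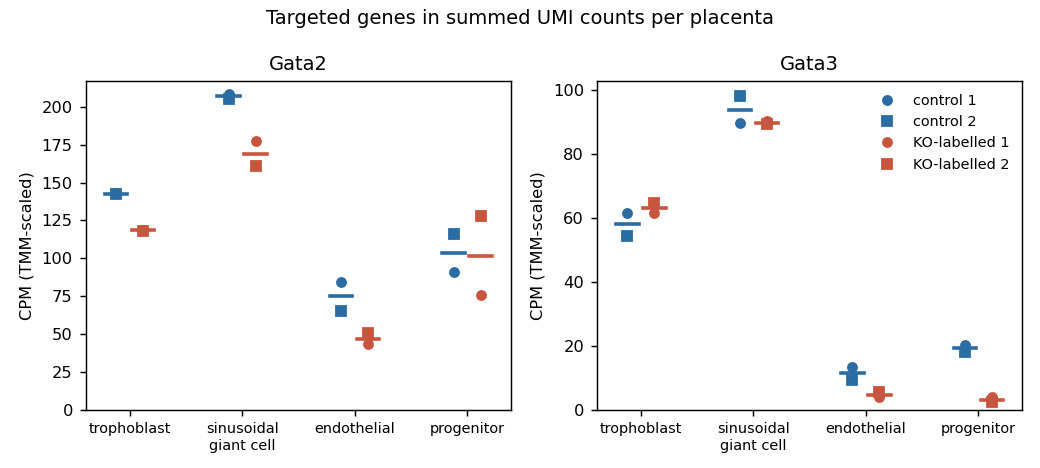
Gata2 and Gata3 in TMM-scaled CPM (y axis) in summed counts of 4 cell classes (x axis), with 1 point per placenta and a line at each group mean. The groups lie close together in trophoblast-like cells, at 143 and 119 CPM for Gata2 and 58.1 and 63.1 CPM for Gata3.

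The KO-labelled placentas yielded more endothelial-like, mesenchyme-like and megakaryocyte-like cells, and fewer progenitor-like and monocyte-like or dendritic-like cells. Endothelial-like cells made up 1.51 and 1.07% of kept barcodes in the controls and 7.38 and 7.53% in the KO-labelled placentas. That was 5.77-fold more (edgeR quasi-likelihood, log2 fold 2.53, SE 0.46, adjusted p = 0.00156). The rise lay in cluster 5, with 8 and 2 control and 409 and 411 KO-labelled cells. Cluster 28, the other endothelial-like cluster, held 72 and 54 control and 74 and 57 KO-labelled cells. Fetal mesenchyme-like or pericyte-like cells rose 16.1-fold, from 0.188 and 0.307% to 4.54 and 3.47% (adjusted p = 0.000312). Megakaryocyte-like or platelet-like cells rose 8.25-fold, from 0.226 and 0.0767% to 1.05 and 1.48% (adjusted p = 0.0019). Haematopoietic progenitor-like cells fell 5.29-fold, from a mean of 4.65% to 0.879% (adjusted p = 0.00349). Monocyte-like or dendritic-like cells fell 5.94-fold, from 13.8 and 10.6% to 2.49 and 1.61% (adjusted p = 0.00156). Natural killer-like or T-like cells averaged 11.2% in the controls and 4.29% in the KO-labelled placentas (log2 fold -1.38, adjusted p = 0.0196). Trophoblast-like cells averaged 43.8 ± 7.15% and 54.3 ± 5.15%, with a log2 fold of 0.31 that did not pass the test (adjusted p = 0.718). Free RNA moved with the first of these groups: the summed endothelial marker list was 2.69 times as abundant in the free RNA of the KO-labelled libraries and 4.38 times in their kept barcodes, and the mesenchymal list 3.42 and 12.0 times. The endothelial sum is held down by Cdh5 (1.78 and 1.24 times) and Esam (1.10 and 1.07 times), and the median over the 13 endothelial markers was 3.54 times in free RNA and 21.2 times in kept barcodes. The median over the 13 mesenchymal markers was 4.22 and 13.3 times. The megakaryocyte list was 1.40 times as abundant in free RNA and 8.84 times in kept barcodes. The sums of other lists did not all follow the shares of their cells. The progenitor list was 1.40 times as abundant in free RNA and 1.30 times in kept barcodes (medians 1.23 and 0.701). Its sum was raised by Cd34 (4.04 and 11.7 times) and Cd93 (4.51 and 20.04 times). Its other members lay between 0.354 (Prtn3) and 2.19 times (Mecom) in kept barcodes, so the sum does not speak for them. The monocyte or dendritic list was at 1.02 and 0.889 times (medians 0.963 and 0.842). The macrophage list was at 1.36 and 1.29 times (medians 1.65 and 1.11), and the neutrophil list at 0.643 and 0.338 times (medians 1.05 and 0.577). The natural killer or T list was at 0.929 and 0.410 times (medians 0.936 and 0.682).

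**Figure D3:**
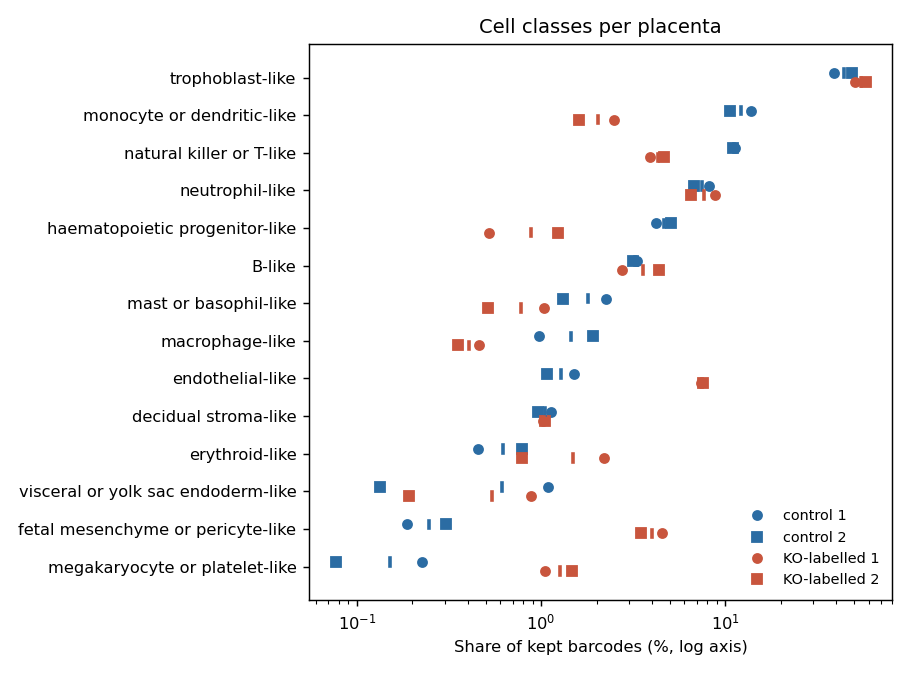
Share of kept barcodes in percent (x axis, log scale) for each cell class, with 1 point per placenta. Endothelial-like cells lie at 1.51 and 1.07% in the controls and at 7.38 and 7.53% in the KO-labelled placentas.

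Leaving out control 2 ended the calls of endothelial-like (adjusted p = 0.0595) and megakaryocyte-like cells (adjusted p = 0.0663), leaving out control 1, control 2 or KO 1 that of progenitor-like cells (adjusted p = 0.0533, 0.0918 and 0.0787), and leaving out any placenta that of natural killer-like or T-like cells (adjusted p between 0.0869 and 0.199). Removing the clusters poor in mitochondrial RNA ended the call of progenitor-like cells (adjusted p = 0.0572), and the stricter cell filter turned the natural killer-like or T-like log2 fold to 1.03. Other settings moved folds by over 1.5 times: the log2 fold of endothelial-like cells was 3.80 with the stricter filter and 3.30 in thinned libraries, that of mesenchyme-like cells 4.66 in thinned libraries, that of megakaryocyte-like cells 4.01 without control 1, and that of progenitor-like cells -3.16 without KO 2 and -2.998 with the stricter filter. For monocyte-like or dendritic-like cells it was -1.72 at Leiden resolution 0.5 and -1.97 in thinned libraries. Unnamed cluster 31 is led by Chil3, Lyz2, Cxcl10 and F13a1 and shares Chil3, Lyz2, Ms4a6d and Ly6c2 with the leading genes of cluster 16. Its best list was macrophage, as was that of unnamed cluster 38, and counting them as macrophage-like was not tried. With cluster 31 counted as monocyte-like or dendritic-like the log2 fold was -1.65 (adjusted p = 0.0113), and with cluster 38, led by Ear2, counted as well it was -1.80 (adjusted p = 0.00723). Different clusters held most of a class in the groups. Cluster 28 held 92.6% of control endothelial-like cells and cluster 5 held 86.2% of KO-labelled ones, clusters 8 and 16 held the control monocyte-like or dendritic-like cells (57.8 and 42.1%) and cluster 29 the KO-labelled ones (93.5%), and clusters 11 and 22 held most control natural killer-like or T-like cells (50.8 and 31.2%) and clusters 33 and 35 most KO-labelled ones (39.2 and 27.5%). The unnamed clusters 12, 13, 21, 31, 32, 36 and 38 held 2.94, 1.61, 2.04, 0.00942, 0.842, 1.43 and 1.46% of control and 2.44, 3.32, 1.36, 1.83, 1.05, 0.226 and 0.0309% of KO-labelled barcodes.

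**Figure D4:**
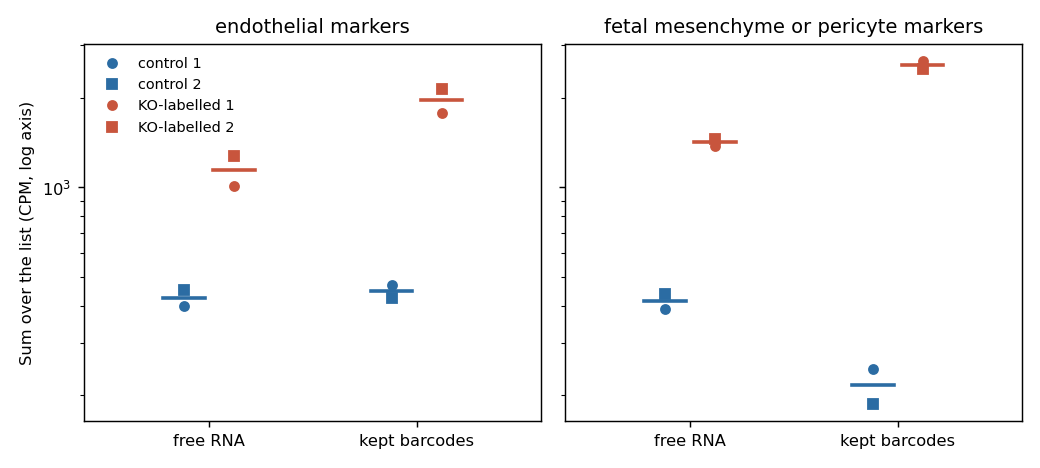
Summed CPM of marker lists (y axis, log scale) in free RNA and in kept barcodes (x axis), with 1 point per placenta. The summed endothelial list, in which Cdh5 and Esam hardly change, is higher in KO-labelled libraries in both fractions, 2.69 times in free RNA and 4.38 times in kept barcodes.

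Within trophoblast, sinusoidal giant cell-like cells, which line the maternal blood sinuses of the labyrinth, were 17.9 and 8.86% of control and 1.51 and 0.610% of KO-labelled trophoblast-like cells. That 12.6-fold lower share did not pass the threshold over the subtypes in edgeR (log2 fold -3.66, SE 0.75, adjusted p = 0.0786). Glycogen trophoblast-like cells were 0.923 and 0.118% against 5.24 and 3.27% (log2 fold 3.06, adjusted p = 0.152), and spongiotrophoblast-like cells averaged 36.8 and 42.2% (adjusted p = 0.455). The summed giant cell list did not follow that share, at 1.08 times the control level in free RNA and 0.722 times in kept barcodes (medians 0.806 and 0.552), and the glycogen list was at 1.58 and 2.11 times (medians 2.04 and 2.51). Prl3b1, at 1.17 and 1.16 times, is the largest member of the giant cell sum. In kept barcodes Ctsm (1.58 times) was higher too, and the other members lay between 0.0150 (Cts6) and 0.937 times (Cts3), with Ctsq at 0.0753 and Lepr at 0.0499. With the replicate block the giant cell-like and glycogen-like differences passed (adjusted p = 0.00273 and 0.00532). The giant cell-like log2 fold was -4.24 (adjusted p = 0.000274) with the stricter filter, -2.96 (adjusted p = 0.0188) at Leiden resolution 0.5 and -2.43 (adjusted p = 0.000303) without the clusters poor in mitochondrial RNA, and ranged from -4.45 to -3.07 with 1 placenta left out. The glycogen-like log2 fold was 3.09 (adjusted p = 0.00949) with the stricter filter and 4.36 (adjusted p = 3.73e-05) without the clusters poor in mitochondrial RNA, and ranged from 2.20 to 5.13 with 1 placenta left out. The spongiotrophoblast-like share depended on the clusters, with a log2 fold of 1.10 (adjusted p = 0.0109) at Leiden resolution 0.5, 1.86 (adjusted p = 0.000689) without the clusters poor in mitochondrial RNA and -0.99 (adjusted p = 0.0738) in thinned libraries. At resolution 0.5 a cluster of 434 and 989 control and 789 and 937 KO-labelled cells was named after parietal giant cells, a trophoblast type known to express Prl3d1, and no cluster was so named at resolution 1.

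In the sums of all clusters named trophoblast-like, genes of type IV collagen and laminin were higher in the KO-labelled placentas, and Lepr, Notch2 and Mdk lower. These sums, and the trophoblast-like shares, leave out unnamed cluster 12, whose best list was syncytiotrophoblast I. They also leave out unnamed clusters 32 and 36, whose best list was labyrinth trophoblast progenitor. At Leiden resolution 0.5 a cluster led by Dio3, Gjb2 and Hsd11b2, as cluster 12 is, was named trophoblast-like. Of 13276 tested genes 3402 were higher and 3273 lower. In spongiotrophoblast-like cells alone, a part of these sums, 38 of 9362 tested genes were higher and 225 lower. The fitted spread between placentas (biological coefficient of variation) was 0.218 there and 0.128 in the whole class. These counts of calls therefore do not compare directly. Different clusters made up the sums: cluster 9 went from 12.1 to 2.12% of trophoblast-like cells and from a mean of 27.0 to 11.1% of their UMIs, cluster 10 from 12.9 to 1.04% and from 26.6 to 4.50%, cluster 2 from 2.08 to 19.4% and from 1.87 to 10.2%, and cluster 24 from 0.477 to 4.22% and from 1.35 to 27.8%. The fit of the sums does not separate such shifts from changes within a cluster. Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826, minus strand) and Col4a2, the paired chains of type IV collagen, rose from 25.4 ± 19.6 to 224 ± 4.16 CPM (log2 fold 3.12, SE 0.44, adjusted p = 0.000871) and from 16.4 to 119 CPM (2.84). Lamb1, a laminin chain, rose from 10.8 to 72.0 CPM (2.72) and Vim, the filament protein of mesenchymal cells, from 13.4 to 85.6 CPM (2.69). Anxa11 rose from 84.7 ± 10.8 to 634 ± 16.2 CPM (2.91, SE 0.14, adjusted p = 2.33e-05) and Dtx1, a Notch pathway ubiquitin ligase, from 12.2 to 79.3 CPM (2.70). Tmem132e, 1600015I10Rik and Hsd17b7 (3.34, 3.20 and 3.14) are leading genes of the glycogen trophoblast-like cluster 24. Aldh1a3 (3.08) stood at 61.5 and 198 CPM in KO 1 and KO 2 against a control mean of 15.5 CPM, and is a leading gene of cluster 1, which held 11.3 and 17.8%.

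Among the lower genes, Lepr, the leptin receptor (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352, plus strand), fell from 181 ± 28.1 to 8.86 ± 2.70 CPM (log2 fold -4.34, SE 0.22, adjusted p = 2.42e-05). Notch2 (ENSMUSG00000027878, chromosome 3, 98013527 to 98150361, plus strand), a receptor of trophoblast lining maternal blood spaces, fell from 243 ± 31.0 to 23.0 ± 0.683 CPM (-3.40, SE 0.13, adjusted p = 1.22e-05). Apoc1, an apolipoprotein gene, fell (-3.49), Mdk, a heparin-binding growth factor, from 263 to 30.3 CPM (-3.12), and Pdgfrb, a receptor for platelet-derived growth factor, from 42.6 to 5.02 CPM (-3.08). B930036N10Rik (-3.53), Tmem267 (-3.36), 1700011M02Rik (-3.33) and AC160336.1 (-3.28) were the others. Ctsq, a cathepsin and a leading gene of the giant cell-like cluster 10, averaged 980 and 90.6 CPM (-3.43). Lepr, Apoc1, Notch2 and AC160336.1 were lower in every other class tested as well, leukocytes included, and AC160336.1, a lincRNA, overlaps Gm5624.

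**Figure D5:**
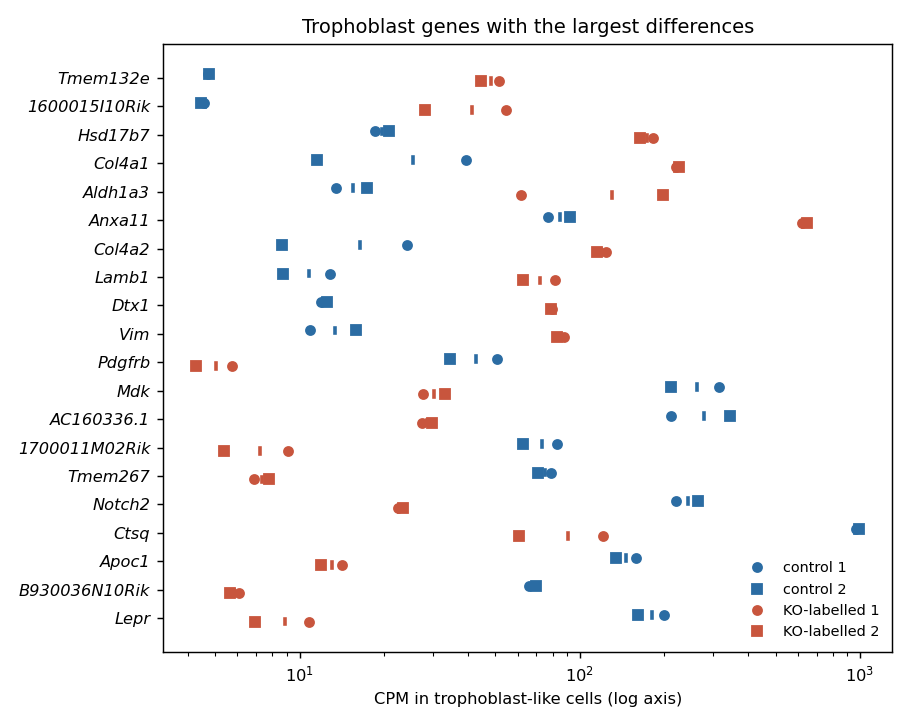
Level in CPM (x axis, log scale) of the 20 genes with the largest differences in trophoblast-like cells, with 1 point per placenta. Lepr lies at a mean of 181 CPM in the controls and 8.86 CPM in the KO-labelled placentas.

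Camera called 4 of the 26 gene lists in trophoblast-like cells, all higher in the KO-labelled placentas, in sums whose largest clusters by UMIs were 9 and 10 in the controls and 24 in the KO-labelled placentas. Of 18 pregnancy-specific glycoproteins, secreted proteins of trophoblast, 16 rose, also when adjusted over the list alone, among them Psg22 (2.54), Psg29 (1.65), Psg27 (1.70) and Psg19 (1.02), and camera gave adjusted p = 0.000489 (adjusted p = 0.835 with an estimated correlation). These genes are near-identical copies, so reads could be split among them. Of 19 genes of the unfolded protein response, 15 rose (15 adjusted over the list alone), among them Asns (1.73), Herpud1 (1.27), Xbp1 (0.88) and Sdf2l1 (0.88), with adjusted p = 0.000893 (adjusted p = 0.749 with an estimated correlation). Of 30 hypoxia genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), among them the prolyl hydroxylase P4ha2 (2.29), the glucose transporter Slc2a1 (1.96), Hk1 (1.38) and Pgk1 (1.34), with adjusted p = 0.0256 (adjusted p = 0.787 with an estimated correlation, and 0.0907 without control 1). Of 24 basement membrane and matrix genes, 16 rose and 3 fell (16 and 3 adjusted over the list alone), among them Hspg2 (1.89), Lamb1 (2.72), Lama5 (1.47) and Col3a1 (4.70, from 1.07 to 27.5 CPM), with adjusted p = 0.000893 (adjusted p = 0.749 with an estimated correlation). The mesenchymal marker list was 3.42 times as abundant in the free RNA of the KO-labelled libraries. Without KO 2 camera called 8 lists.

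In sinusoidal giant cell-like cells, prolactin-family hormone genes were higher in the KO-labelled placentas (8 of 11 rose, camera adjusted p = 0.00161; adjusted p = 0.486 with an estimated correlation), and Cts6 and Fos were lower. Of 9497 tested genes 1408 were higher and 1555 lower, from 369 and 226 control and 50 and 22 KO-labelled cells. Prl2c5 rose from 95.3 ± 39.6 to 1623 ± 985 CPM (log2 fold 4.07, SE 0.41, adjusted p = 0.000105) and Prl3b1, placental lactogen 2, from 663 ± 658 to 6489.8 ± 2846 CPM (3.29, SE 0.62, adjusted p = 0.00347). Col4a1 (3.50), Fbxo32 (3.45), Col4a2 (3.15), Prl2c3 (3.08), Tnfrsf9 (2.90, from 16.9 to 129 CPM), Flt1 (2.74), Maged2 (2.36) and Fblim1 (2.34) were the other named higher genes. The immediate-early gene Fos fell from 131 ± 1.77 to 15.8 ± 0.785 CPM (-3.04, SE 0.15, adjusted p = 4.7e-06). The heat shock genes Hspa1a (-2.90) and Hspa1b (-2.85, from 267 to 37.3 CPM) were also lower. Cts6 (-4.64, from 46.7 ± 36.2 to 1.98 CPM), AC160336.1 (-3.01), Tmem267 (-2.95), Rpgrip1 (-2.80) and Cox7a1 (-2.57) were also lower. AC160336.1, Rpgrip1 and Cox7a1 were lower in every class tested. At Leiden resolution 0.5, which groups these cells with others, Prl2c5, Fbxo32, Prl3b1 and Prl2c3 turned to -1.50, -0.28, -0.65 and -3.63, and Tnfrsf9 (0.20, adjusted p = 0.627) and Fblim1 (0.44, adjusted p = 0.256) no longer passed. The Wald test of DESeq2 gave 1616 genes in these cells, and Leiden resolution 0.5 gave 5045.

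Camera called 7 lists in these cells, each with adjusted p = 0.486 with an estimated correlation. Of 11 prolactin-family hormones 8 rose (8 adjusted over the list alone), with Prl2b1 at 1.57 and Prl7d1 at 2.29 beside Prl2c5 and Prl2c3 (adjusted p = 0.00161). Of 49 G2M cell cycle genes 27 rose and 5 fell (30 and 6 adjusted over the list alone), with Mki67 at 1.84, Cenpe at 1.54, Tubb4b at 1.26 and Smc4 at 1.09 (adjusted p = 1.61e-06). Of 42 S-phase genes 11 rose and 5 fell (11 and 5 adjusted over the list alone), with Prim1 at 1.04, Clspn at 1.00, Tyms at 0.91 and Ccne2 at -1.20 (adjusted p = 0.0439). Of 12 basement membrane and matrix genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with Lamb1 at 2.50 and Sparc at 1.18 beside the collagen IV genes (adjusted p = 0.0165). Of 6 haematopoietic niche factors 3 fell (4 adjusted over the list alone): Jag1, a Notch ligand, at -1.65, Tgfb2 at -1.44 and Igf2 at -0.78, with Tgfb1 at -0.35 (adjusted p = 0.069), and the list had adjusted p = 0.0369. Of 5 measured genes of the endothelial-to-haematopoietic programme 4 fell (4 adjusted over the list alone): the stem cell factor receptor Kit at -1.22, Meis1 at -1.12, Ikzf2 at -1.03 and Cbfb at -0.86 (adjusted p = 0.0129). Of 3 myeloid granule genes 2 fell (3 adjusted over the list alone), S100a8 and S100a9, with Prtn3 at -1.41 (adjusted p = 0.0563), and the list had adjusted p = 0.0284. S100a8 (-3.73) and S100a9 (-3.33) had 0 counts left in each placenta with free RNA subtracted and were 0.484 and 0.743 times as abundant in the free RNA of the KO-labelled libraries, so their fall and that of the list are not read as changes in these cells. With free RNA subtracted Col4a1 stood at 6.48 and Col4a2 at 4.18, with 0 counts of both left in control 2. The call of niche factors ended without KO 1 (adjusted p = 0.246), that of Flt1 without KO 1 (1.21, adjusted p = 0.254), and that of S-phase genes with the replicate block (adjusted p = 0.0655) and without control 1, KO 1 or KO 2 (adjusted p = 0.154, 0.0800 and 0.0920).

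In endothelial-like cells Nid2 was higher in the KO-labelled placentas, and transcripts known from trophoblast, such as Tpbpa and Prl7a2, were lower. Subtraction of free RNA took few of the Tpbpa and Prl7a2 counts of the controls and all of those of KO 1, the lower group. Free RNA so estimated therefore does not account for their higher level in the controls. Different clusters held most cells of the groups, so these transcripts are not read as changes of endothelial cells. Of 11689 tested genes 577 were higher and 591 lower, from 309927 and 113140 UMIs in the control sums and 15429230 and 15264620 in the KO-labelled sums. Most control cells were in cluster 28, with medians of 1552 UMIs and 0.387% mitochondrial UMIs. Most KO-labelled cells were in cluster 5, with medians of 28460 UMIs and 5.56%. The fit of the sums does not separate this difference in make-up from changes within a cluster. Nid2, a basement membrane protein, averaged 46.6 ± 13.3 CPM in the controls, from 11 and 6 counts, and 437 ± 0.880 CPM in the KO-labelled placentas (log2 fold 3.35, SE 0.22, adjusted p = 0.0056). Arap2 (ENSMUSG00000037999, chromosome 5, 62602445 to 62766159, minus strand) had 0 counts in the controls and 1391 in the KO-labelled placentas, at least 5.81-fold higher (adjusted p = 0.014). Clspn had 1 control count against 1718 (ratio 21.5, 95% interval 3.86 to 850), Clec1b 2 against 2299 (14.4, 3.98 to 119), Kif23 2 against 2068 (12.95, 3.58 to 107) and Oit3 3 against 2152 (8.98, 3.07 to 43.6). Gpr1 (16.5, 2.96 to 654), Brip1os (15.0, 2.69 to 594) and Adcy9 (9.98, 2.76 to 82.5) rested on 1 or 2 control counts as well. Enpp2 leads cluster 5, which holds most KO-labelled cells, and averaged 42.9 and 554 CPM (4.06). Tpbpa, a spongiotrophoblast gene, averaged 5262 ± 3912 CPM in the controls and 273 CPM in the KO-labelled placentas (-4.25, SE 0.54, adjusted p = 0.0101), and Tpbpb (-4.34), Prl7a2 (-4.83, from 331 to 9.89 CPM), Psg18 (-4.28), Sbsn (-4.85) and Pgf, placental growth factor (-5.62, from 109 ± 111 to 1.74 CPM), went the same way. With free RNA subtracted Tpbpa kept 726 and 851 control counts, 0 of 4694 in KO 1 and 2918 of 4095 in KO 2. Tpbpb, Prl7a2, Psg18 and Sbsn also kept 0 counts in KO 1, while Pgf kept 32 of 40. The sizes of these differences therefore depend on that subtraction. Bhlhe41 (-5.21), Serpine1 (-4.48), S100a8 (-4.31) and Cd14 (-4.30) were the other named lower genes. With free RNA subtracted S100a8 kept 38 and 1 control and 0 and 4 KO-labelled counts, so it is not read as a change in these cells. Bhlhe41 kept 5 and 7 against 0 and 12, and Cd14 26 and 1 against 0 and 74.

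Camera called 6 lists there. The prolactin, glycoprotein and cathepsin lists hold transcripts known from trophoblast, so their falls are not read as changes of endothelial cells. Prl7a2 kept 0 of 208 counts in KO 1 with free RNA subtracted, and 74 of 110 in KO 2. Prl3b1 stood at 2511 and 2538 CPM in the free RNA of the controls and 3240 and 2681 CPM in that of KO 1 and KO 2. Of 52 G2M genes 15 rose (23 adjusted over the list alone), with Top2a at 2.53, Mki67 at 2.38, Smc4 at 1.48 and Tubb4b at 1.41 (adjusted p = 0.0029; adjusted p = 0.754 with an estimated correlation), and of 42 S-phase genes 8 rose (24 adjusted over the list alone), with Mcm5 at 2.27, Tyms at 1.29 and Nasp at 1.11 beside Clspn (adjusted p = 0.00292; adjusted p = 0.754 with an estimated correlation). Of 12 prolactin-family hormones 7 fell (8 adjusted over the list alone), with Prl8a9 at -3.73, Prl8a8 at -3.13 and Prl3b1 at -3.09 beside Prl7a2 (adjusted p = 3.63e-06; adjusted p = 0.81 with an estimated correlation). Of 13 pregnancy-specific glycoproteins and relatives 9 fell (11 adjusted over the list alone), with Ceacam14 at -3.67, Ceacam11 at -3.54, Ceacam13 at -3.42 and Psg21 at -3.27 (adjusted p = 2.01e-09; adjusted p = 0.81 with an estimated correlation). Of 5 placental cathepsins 2 fell (4 adjusted over the list alone), Cts3 at -3.76 and Ctsm at -3.18, with Ctsr at -4.08 (adjusted p = 0.0837) and Ctsq at -4.11 (adjusted p = 0.0842), and the list had adjusted p = 0.000458 (adjusted p = 0.754 with an estimated correlation). Of 24 immediate-early and dissociation genes 3 fell and 1 rose, also when adjusted over the list alone: Ier3 at -2.89, Dnajb1 at -1.75, Cyr61 at -1.34 and Hspa8 at 0.89 (adjusted p = 0.00925; adjusted p = 0.81 with an estimated correlation).

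Cluster 28 alone, which had at least 20 cells in each placenta, gave 0 calls in edgeR among 2817 genes (267 at an unadjusted p under 0.05), and the edgeR fit without a filter on low counts also gave 0 calls, while the Wald test of DESeq2 on the whole class gave 1589 (542 higher and 1047 lower). With the trend with transcript length removed 366 genes passed, 49 higher and 317 lower. Leaving out control 1, KO 1 or KO 2 changed the count from 1168 to 773 (363 higher), 324 (101 higher) or 359 (115 higher), and without control 1 the S-phase and G2M lists had adjusted p = 0.609 and 0.378, Serpine1 0.352, S100a8 0.434, Cd14 0.847, Gpr1 0.110, Brip1os 0.361 and Adcy9 0.196. Without control 2 the immediate-early list had adjusted p = 0.167, Pgf 0.0527 and Cd14 0.0534, and without KO 1 or KO 2 Gpr1 (0.176 and 0.0676), Brip1os (0.187 and 0.210), Adcy9 (0.0704 and 0.102), Bhlhe41 (0.684 and 0.661) and Psg18 (0.133 and 0.134) no longer passed.

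In haematopoietic progenitor-like cells, all in cluster 14, Hspb1 and Mfsd11 were among the lower genes in the KO-labelled placentas. Of 9759 tested genes 819 were higher and 1357 lower, from 223 and 266 control and 34 and 77 KO-labelled cells. The small heat shock protein gene Hspb1 fell from 379 ± 80.0 to 9.14 ± 2.66 CPM (log2 fold -5.25, SE 0.22, adjusted p = 1.86e-06). The chemokine genes Ccl5 (-4.30, from 205 to 16.3 CPM) and Cxcl2 (-4.17, from 109 to 5.87 CPM) and the granule gene S100a9 (-4.73, from 227 to 8.38 CPM) were lower as well. These genes lead clusters of other cells, Hspb1 the trophoblast-like cluster 6, S100a9 the neutrophil-like cluster 26, Ccl5 the natural killer-like or T-like cluster 41 and Cxcl2 a neutrophil-like cluster at Leiden resolution 0.5, and subtraction of free RNA took 7.58, 15.5, 16.0 and 9.83% of the UMIs of these sums. S100a9 then had 0 counts left in each placenta and Cxcl2 7 and 136 in the controls and 0 in the others, too few for the fit, so neither is read as a change in progenitor-like cells. Hspb1 kept 368 and 427 control counts and Wfdc17 26 and 55, with 0 in both KO-labelled placentas, and Ccl5 kept 554 and 261 control counts against 17 and 0, so the sizes of their falls depend on that subtraction. Klf1, a marker of the erythroid list, is a leading gene of cluster 14. Globin made by these cells may therefore have inflated the amount subtracted, and the counts left are no firm measure. Without doublet removal Ccl5 stood at -2.17, Cxcl2 at -2.30 and S100a9 at -2.57, and the call of Ccl5 ended in the Wald test of DESeq2 (adjusted p = 0.149). Olfr655 had 195 counts in the controls and 2 in the KO-labelled placentas, a ratio of 106 (95% interval 28.9 to 880). Olfr1369-ps1 (-5.07), Mfsd11 (-3.77), Snhg9 (-3.74), AC160336.1 (-3.65) and Wfdc17 (-3.51) were also lower, and Snhg9, AC160336.1 and Wfdc17 were lower in every class tested. Higher genes changed less: Ptgs1, a cyclooxygenase of platelets and their precursors, rose from 11.2 to 33.8 CPM (1.57), Cops5 from 42.7 to 125 CPM (1.54, SE 0.16, adjusted p = 0.000166), and Ccdc22 (1.48), Cenpb (1.47), Rnf26 (1.43), Zbtb12 (1.39), Aven (1.36), Trappc12 (1.33), Bckdha (1.29) and Eif2b5 (1.28) rose too. Camera called 0 of 24 lists (5 at an unadjusted p under 0.05). fry does not compare a list with other genes, and camera with an estimated correlation called 0 as well. Camera called 4 lists with the replicate block, 6 without KO 1 and 3 without KO 2. The Wald test of DESeq2 gave 1026 genes, and subtraction of free RNA left 1433. Without control 1 the gene count was 1059, without control 2 it was 958, and Bckdha no longer passed in either (adjusted p = 0.0554 and 0.0709). Mpo, a granulocyte precursor gene among the markers of this class, stood at 177 and 139 CPM in the controls and at 139 and 970 CPM in KO 1 and KO 2.

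Macrophage-like cells, all in cluster 34, were of a different kind in the groups, so neither their share nor their genes are compared as regulation. C1qa stood at 18.6 and 3.35 CPM in the controls and 1774 and 571 CPM in the KO-labelled placentas, and Lyve1, a marker of fetal-type tissue macrophages, had 0 control counts and 53 KO-labelled counts, at least 28.5-fold higher. Of 5211 tested genes 336 were higher and 477 lower. Gas6 (at least 127-fold), Ltc4s (at least 35.5-fold), Igf1 (at least 26.3-fold), Slco2b1 (at least 18.3-fold) and Folr2 (at least 15.0-fold) had 0 control counts, Pf4 had 2 against 1310 counts (ratio 1056, 95% interval 292 to 8729.7), and Stab1 averaged 6.29 and 577 CPM. Fcrls and Mrc1 lead the cluster itself. Other genes had few counts in the KO-labelled placentas: S100a8 had 5993 against 3 counts (ratio 1239, 424 to 6009.6), S100a9 2890 against 2 (896, 248 to 7404), G0s2 156 against 1 (96.8, 17.1 to 3846), H2-Aa 120 against 1 (74.4, 13.1 to 2964) and H2-Ab1 116 against 1 (71.9, 12.7 to 2866). Stfa3, H2-Eb1, Snhg9 and Lilrb4a had 0 KO-labelled counts (at least 46.9-fold, 19.4-fold, 14.1-fold and 10.5-fold lower), and Lepr averaged 257 and 4.55 CPM (-5.43). Camera called 0 of 24 lists, with 4 at an unadjusted p under 0.05, 0 with an estimated correlation, 3 with the replicate block, 2 without control 1, 3 without control 2 and 5 without KO 2. The Wald test of DESeq2 gave 434 genes and the fit without a filter on low counts 1246. Without control 1 the gene count was 80, without control 2 it was 276 and without KO 2 it was 1363, and without control 1 Ltc4s, Slco2b1, Folr2, Stfa3, H2-Eb1, Lilrb4a and H2-Ab1 no longer passed (adjusted p = 0.0718, 0.0685, 0.0609, 0.0578, 0.0936, 0.0867 and 0.0718).

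The group effect differed between endothelial-like and trophoblast-like cells for 1805 of 13892 genes (1149 with a higher and 656 with a lower log2 fold in endothelial-like cells, edgeR interaction term with placenta as block). Nid2 had a log2 fold higher by 2.08 in endothelial-like cells (adjusted p = 0.000205), and Enpp2 by 2.39. Tpbpa had a log2 difference of -4.50, with a log2 fold of 0.60 in trophoblast-like and -4.25 in endothelial-like cells, and Tpbpb of -4.33. With free RNA subtracted, both kept 0 counts in endothelial-like cells of KO 1 and nearly all of their counts in those of the controls. Gata2 and Gata3 had log2 differences of -0.32 (adjusted p = 0.589) and -1.32 (adjusted p = 0.304). With cluster 28 as the only endothelial-like cluster, 62 genes differed.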

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

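The tests on thinned libraries, on free RNA against kept barcodes, on the level of Gata2 and on short transcripts in leukocytes were chosen only after the result was seen. The difference of the group effect between endothelial-like and trophoblast-like cells was called by the interaction term for 1805 genes, and 25 of the named genes were among them. Trophoblast transcripts had a lower log2 fold in endothelial-like than in trophoblast-like cells: the log2 difference was -4.33 for Tpbpb, -4.50 for Tpbpa, -4.99 for Sbsn, -6.79 for Pgf, -4.34 for Prl7a2 and -4.45 for Psg18. With free RNA subtracted, endothelial-like cells of KO 1 kept 0 counts of Tpbpb, Tpbpa, Sbsn, Prl7a2 and Psg18. The controls kept nearly all of theirs, so free RNA so estimated does not account for the differences. Different clusters held most endothelial-like cells in the groups, so these differences are not read as regulation in endothelial cells. The log2 difference was -4.59 for Serpine1, -4.39 for Bhlhe41, -2.01 for S100a8 and -3.36 for Cd14. For Vim, Col4a2, Col4a1 and Anxa11 it was -1.68, -1.49, -1.53 and -2.04. It was above 0 for AC160336.1 (1.87), Mdk (1.67), Enpp2 (2.39), Nid2 (2.08), Tmem267 (4.17) and B930036N10Rik (2.39). The fitted values of Arap2 (13.37), Pdgfrb (11.60), Clspn (4.40), Kif23 (3.10) and Brip1os (3.63) rest on few control counts in endothelial-like cells and are no bounds.

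Data outside the cells separated the groups too. Mitochondrial transcripts were 10.8% of the free RNA in the KO-labelled libraries and 3.85% in the controls (group means). The endothelial marker list was 2.69 times and the mesenchymal list 3.42 times as abundant in the free RNA of the KO-labelled libraries as in that of the controls.

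The first pattern is the higher yield of endothelial-like and mesenchyme-like cells in the KO-labelled placentas, for which deeper sequencing is argued against, since with all libraries thinned to equal totals the smaller of the log2 folds was 3.30. Loss of intact endothelial and mesenchymal cells in the control preparations may account for a part. The KO over control ratio of the marker UMIs was 1.63 times as high in kept barcodes as in free RNA for the endothelial list and 3.50 times for the mesenchymal list, where over 2 for both lists had been set as the mark of such loss and at most 1 as the mark against it. By single marker, 10 of 13 endothelial and 10 of 13 mesenchymal genes lay over 2 (medians 5.80 and 2.91) and 2 of each list at most at 1, so the endothelial sum, in which Cdh5 and Esam weigh most in the controls, does not speak for its members and such loss stays open. Deletion of Gata2 and Gata3 stays open and cannot be told apart from a difference in preparation, because the log2 fold of Gata2 in trophoblast-like cells was -0.27 in a tag whose place relative to the deleted part is not known, and all libraries of a group share 1 label.

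The second pattern is the shortage of short transcripts in every class tested of the KO-labelled placentas. Deletion acting inside trophoblast is argued against as its cause: in 4 leukocyte classes the median log2 fold of transcripts of at most 500 nt against those of 2000 to 4000 nt was -1.53 or lower. Of these, neutrophil-like and monocyte-like or dendritic-like cells held Xist in male and female placentas alike, which marks them as largely maternal. Xist values of the other leukocyte classes are not given here. The median in trophoblast-like cells of the thinned libraries was -0.82, against -0.66 on the same measure before thinning. Thinning lowers all genes of a library by the same factor, so this test cannot decide whether deeper sequencing plays a part. A library or handling difference between the groups is a candidate explanation, because free RNA, which belongs to no class, showed a median of -1.02. The threshold for that test, not the value, was set out before it was run. Lepr, Apoc1 and Notch2, with longest transcripts of 5542, 532 and 10500 nt, were lower in every class tested, and their cause was not tested.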

How the results depend on the processing

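The tests with thinned libraries, without mitochondria-poor clusters, on shared endothelial-like clusters, with the transcript length trend removed, and with unnamed clusters counted as monocyte-like, were chosen only after the result was seen. The single named results kept direction and side of the threshold in 1822 combinations of result and setting, passed newly in 11, no longer passed in 137 and turned direction in 44. Where no reason is given below, the cause was not tested. In fits that leave an arm with 1 placenta, that placenta was assumed to vary like the other group. The stricter filter could not be run in endothelial-like and macrophage-like cells, nor the mitochondrial limit of 10% in giant cell-like cells, nor thinning in macrophage-like cells, since under 20 cells were left in a placenta. Replicate numbers followed fetal sex, and the main fits did not model them. Without sex-linked genes, the log2 CPM difference between placentas 2 and 1 was correlated between the groups in some classes. The correlation was 0.348 in trophoblast-like, 0.499 in spongiotrophoblast-like and 0.224 in erythroid-like cells, and -0.0662 to 0.0874 in the other classes fitted. Endoderm-like cells numbered 58 and 7 in the controls and 58 and 12 in KO 1 and KO 2. What lies behind this was not tested.

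Leaving out each placenta gave 5264 to 5926 genes in trophoblast-like, 2159 to 2426 in giant cell-like, 324 to 1737 in endothelial-like, 958 to 2690 in progenitor-like and 80 to 1363 in macrophage-like cells. The log2 folds ranged for Gata2 from -0.28 to -0.26 in trophoblast-like, -0.37 to -0.23 in giant cell-like, -0.95 to -0.52 in endothelial-like and -0.44 to 0.31 in progenitor-like cells. For Gata3 they ranged from 0.02 to 0.20, -0.13 to -0.01, -1.50 to -1.04 and -3.02 to -2.23. Camera called 4 to 8 lists in trophoblast-like, 5 to 10 in giant cell-like, 4 to 8 in endothelial-like, 0 to 6 in progenitor-like and 0 to 5 in macrophage-like cells. Class shares gave 2 to 5 calls and trophoblast subtypes 0 to 0. Prl3d1 in trophoblast-like cells ranged from -0.66 to 0.65, turning without control 1, and Gata2 in progenitor-like cells to -0.13 without control 1 and -0.44 without KO 2. Class shares near 0 turned as well: decidual stroma-like (0.11 without control 1, 0.0016 without KO 1), unnamed (-0.33 to 0.35, turning without control 1 and, at 0.25, without KO 2), endoderm-like (-1.66 to 1.99, turning without control 1 and, at 0.53, without KO 2), neutrophil-like (-0.09 without control 2, -0.18 without KO 1), B-like (-0.24 to 0.44, turning without KO 2) and spongiotrophoblast-like (-0.026 without control 1).

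The replicate block gave 4 lists in progenitor-like and 3 in macrophage-like cells, 2 subtypes, and -0.033 for Gata2 in progenitor-like cells. With an estimated correlation 0 lists were called in trophoblast-like, giant cell-like and endothelial-like cells. The Wald test of DESeq2 gave 1616 genes in giant cell-like, 1026 in progenitor-like and 434 in macrophage-like cells, with Gata2 at -0.28 and -0.29 in trophoblast-like and giant cell-like cells, no longer passing. Without a filter on low counts, endothelial-like cells gave 0 genes and macrophage-like cells 1246, and Gata2 in trophoblast-like cells stood at -0.22, no longer passing. TMM factors over the subtypes turned the trophoblast without a subtype to -0.021.

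With free RNA subtracted, progenitor-like cells gave 1433 genes, Gata3 stood at -7.93 there with 0 KO-labelled counts left, S100a9 and Cxcl2 there and S100a8 and S100a9 in giant cell-like cells could not be fitted, and Gata2 stood at -0.26 in trophoblast-like and -0.29 in giant cell-like cells, no longer passing. With a mitochondrial limit of 10% Gata2 stood at -0.24 in trophoblast-like cells, no longer passing. Without doublet removal it stood at -0.20, no longer passing, Prl3d1 turned to 0.20, Gata3 in giant cell-like cells to 0.15, Stfa3 in macrophage-like cells to 0.46 and the neutrophil-like share to -0.019, and Gata3 in progenitor-like cells stood at -1.20 (adjusted p = 0.0995). The stricter filter left Gata2 at -0.29 in giant cell-like cells, no longer passing, gave 2 subtypes, and turned the shares of basophil-like (0.59), natural killer-like or T-like (1.03), neutrophil-like (-0.57) and trophoblast-like cells (-0.034).

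At Leiden resolution 0.5, which draws the classes differently, giant cell-like cells gave 5045 genes, Prl2c5 (-1.50), Fbxo32 (-0.28), Prl3b1 (-0.65) and Prl2c3 (-3.63) turned there, and Gata2 stood at -0.10, no longer passing. Gata2 in trophoblast-like cells turned to 0.042, the neutrophil-like share to -0.90 and the unnamed to 0.40, and 2 subtypes were called. Thinned libraries turned the neutrophil-like (-1.16, adjusted p = 0.0330), trophoblast-like (-0.046), unnamed (0.59), endoderm-like (0.42) and spongiotrophoblast-like shares (-0.99). Without mitochondria-poor clusters 4 classes and 4 subtypes were called, Prl3d1 turned to 0.30, and the decidual stroma-like (0.41), trophoblast-like (-0.50), unnamed (0.40), endoderm-like (0.24) and subtype-free trophoblast shares (-0.88) turned. Cluster 28 alone gave 0 genes in endothelial-like cells and 62 for the difference between both classes. With the length trend removed endothelial-like cells gave 366 genes (49 higher and 317 lower), Prl3d1 turned to 0.26, Gata3 in trophoblast-like cells to -0.00052 and Gata2 in progenitor-like cells to -0.090, and 5887 of the 6675 trophoblast-like calls were shared with the 6586 calls of that fit. Of the 5 classes simulated, endothelial-like and macrophage-like cells had the lowest recovery of 2-fold changes, 37% and 20%, and the part of depth in that was not separated from the spread between placentas.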

Other observations

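The tests of a germline variant and of an interferon response for Trim12a were chosen only after the result was seen. Neutrophil-like cells of the KO-labelled placentas held more inflammatory and hypoxia transcripts. Of 15 inflammatory cytokine genes 12 rose and 2 fell (12 and 2 adjusted over the list alone), among them the interleukin genes Il1b (log2 fold 2.07, from 4316 to 18160 CPM) and Il1a (3.38, from 17.6 to 188 CPM), the prostaglandin synthase Ptgs2 (2.75) and Nfkbia (1.74), with a camera adjusted p = 0.000538 (adjusted p = 0.638 with an estimated correlation). Of 26 hypoxia genes 15 rose and 1 fell (17 and 2 adjusted over the list alone), with Vegfa at 1.69, Egln3 at 2.40, Bnip3 at 1.10 and Eno1 at 1.07 (adjusted p = 0.00103; adjusted p = 0.638 with an estimated correlation). Of 23 immediate-early and dissociation genes 17 rose and 6 fell, with Egr1 at 2.95, Junb at 2.09, Dusp1 at 1.86 and Btg2 at 1.79 (adjusted p = 0.00534; adjusted p = 0.638 with an estimated correlation). Different clusters held these cells, 17 and 26 in the controls (64.2 and 33.5%) and 4 in the KO-labelled placentas (96.8%). The mitochondrial share of the free RNA, 10.8 against 3.85%, moved with the same groups.

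In mast cell-like or basophil-like cells Gata2, a factor these cells need, rose from 911 ± 52.8 to 2032 ± 187 CPM (log2 fold 1.15, SE 0.19, adjusted p = 0.00492). H2-Eb1 and Cd74, genes of class II antigen presentation, were lower. H2-Eb1 had 148 counts in the controls and 0 in the KO-labelled placentas, at least 56.1-fold lower, and Cd74 averaged 1269.6 and 22.9 CPM (-6.07). In erythroid-like cells that escaped the red-cell depletion, 8 of 17 globin and haem genes rose (10 adjusted over the list alone), with the embryonic globin Hbb-bh1 at 2.97, Fech at 2.75, Alas2 at 2.37 and Car2 at 1.93 (adjusted p = 0.00148; adjusted p = 0.706 with an estimated correlation). In natural killer-like or T-like cells 8 of 23 G2M genes fell (10 lower and 1 higher adjusted over the list alone), with Birc5 at -2.53, Ube2c at -2.03, Hmgb2 at -1.75 and Cks2 at -1.27 (adjusted p = 0.000162; adjusted p = 0.886 with an estimated correlation). Decidual stroma-like cells gave 0 calls in edgeR among 4359 genes, with 735 at an unadjusted p under 0.05, and no other tool was run there. The other settings were also not run on the gene fits of neutrophil-like, mast cell-like or basophil-like, erythroid-like and natural killer-like or T-like cells.

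The replicate numbers followed the sex of the fetus. In trophoblast-like cells Xist stood at 1727 and 5.65 CPM in control 1 and control 2 and at 678 and 2.79 CPM in KO 1 and KO 2, while the Y-linked gene Ddx3y stood at 0, 38.2, 0.342 and 43.5 CPM. Neutrophil-like cells held Xist in all 4 placentas (696, 564, 442 and 290.0 CPM), as did monocyte-like or dendritic-like cells (1298, 1294, 1068 and 946 CPM), as maternal cells of a male fetus's placenta would.

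The third pattern is Trim12a (ENSMUSG00000066258, chromosome 7, 104299894 to 104315466, minus strand), a gene chosen after its values were seen, which over 4 leukocyte classes stood at 0.180 and 0.553 CPM in the controls and at 59.4 and 53.1 CPM in the KO-labelled placentas, 3 against 545 counts (ratio 173, 95% interval 59.0 to 843). A general interferon response is argued against, since the highest median log2 fold of the interferon list over those classes was 0.45, and so are reads moved from Trim12a to its paralog Trim12c, since Trim12c was not higher in the controls (controls minus KO -60.0 CPM). A germline variant that differs between the dams of the groups may account for it: in endothelial-like cells KO 1 held 18.7 times the Trim12a of KO 2 (265 against 14 counts). This reading takes those cells to be fetal, since fetuses can carry different alleles, and their origin was not shown here. The 0 counts of the shallow control sums allow a bound of only at least 1.28-fold there, and trophoblast-like cells held 2 against 12 counts (ratio 2.88, 95% interval 0.642 to 26.5). The labels used here name neither dams nor litters, so such a variant is a hypothesis.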
